A study of Homo sapiens with 6 samples.

How the data were processed

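Expression was measured by 3′ mRNA sequencing with an oligo-dT, strand-keeping kit on an Illumina sequencer, per the labels' protocols, in 3 control and 3 OLA1 siRNA libraries of primary human pulmonary arterial endothelial cells. Groups and replicate numbers were taken from the sample titles, and the columns of the gene table were matched to the samples by their names. The protocol in the labels describes transfection for 24 h and rest for 24 h for the samples, while the transfection entry of the controls reads none. No per-sample column was left unused.

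The main values were gene-level FPKM deposited by the authors in 1 table of 48378 rows with Ensembl gene identifiers. The submitters' processing notes name HISAT2 and StringTie, but the tool, annotation and genome build behind this table are not given in the sources used here. Of the identifiers, 48145 matched a symbol. A value was present in all 6 libraries for 36536 rows, in 1 to 5 libraries for 3827 rows and in none for 8015 rows. The empty cells made up 20.26% of the table, 4.64% for genes with 1 annotated transcript in GENCODE v29 and 86.66% for genes with 5 or more, so many multi-transcript genes have no value. Of 11759 protein-coding rows, 4265 had 6 values. The rows used did not include OLA1, which was not analysed here from this table. FPKM divides by gene length, although a 3′ kit reads transcript ends whatever their length, so levels of different genes are not comparable, while ratios between libraries of 1 gene are unaffected.

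FPKM holds no counts, and no count model was used. In genes with 1 annotated transcript the values came in steps. After correction for relative depth, 25.8% of 19340 ratios between libraries lay within 0.2% of a ratio of whole numbers up to 6, against 2.8% with the depths shifted by 7%. The steps placed the relative depth of the libraries between 0.797 and 1.193 times that of control replicate 1, and the size of the step in genes with exons over 4000 bases in all placed the reads at about 5990000 to 8970000 per library. These are approximate, and reads per gene estimated from them were used to judge depth and to choose the genes of 2 added fits and of the check of zeros, but not as counts in a test. Among 1330 tested genes with 30 reads or more once the estimate is rounded to 1 decimal (1328 unrounded, as in the added fits), 156 had a value of 0 in 1 library or more, which sampling alone would not give, so a value of 0 was read as listed at 0.

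The other deposited files are transcript tables of StringTie 2.1.3b for each library, with coverage, FPKM and TPM per reference transcript on GRCh37 with RefSeq annotation and the --fr strand setting, per the file headers. Of 81203 transcripts, 1117 to 1772 were above 0 in a library. The 9 light-strand genes took 79.15% to 84.92% of the bases on the mitochondrial genome, and of the 99 most abundant protein-coding genes of the gene table that could be looked up, 89 were at 0 in all 6 files. These values were taken to come from the strand opposite to most mRNAs, as a stranded kit read with the opposite setting gives, and served for alternatives fixed beforehand, for gene coordinates, for the values of OLA1 and of abundant transcripts, and for a look-up of the list genes reported with the closing observations.

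Genes with 6 values and a mean of at least 1 FPKM over the 6 libraries were tested, 3013 in all. Values were log2(FPKM + 1), fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with trend, no covariate), two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. With 3 against 3 an exact permutation test cannot go below 0.1, so the evidence rests on the model over all genes. Gene lists with at least 5 measured members were tested with camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 4 lists, and again with an estimated correlation and with fry. Calls within a list were also adjusted over the list alone. The tests, the 42 lists, the alternatives and the rule for named genes were fixed before the data were examined, except those said below to be added. The rule names OLA1, the 10 largest rises and the 10 largest falls among called genes whose groups do not overlap, and up to 4 called members of each list that passed or had called members, or the 2 members with the highest mean FPKM of a passing list without calls; genes without an official symbol, XIST and Y-linked genes were left out. It gave 25 genes besides OLA1. Other software was Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

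The fit was tested on simulated data with the means and residual spread of the 3013 genes and 200 changed genes. It recovered 56.7% of changes of 1 on the log2 scale, 74.6% of changes of 2 and 80.3% of changes of 3, with 10 false calls, and made 0 calls by limma without any change. The camera test gave a p of 1.91e-12 for a list of 8 genes raised by 1 and a p of 0.124 for a list of 8 unchanged genes. The changed genes and both lists were drawn from genes with a mean log2(FPKM + 1) above 3, so the recovery of lower genes was not tested. The simulated genes varied independently, so the behaviour of camera with correlated genes was not tested either.

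The alternatives fixed beforehand were a pseudocount of 0.1, no expression filter, a mean of at least 5 FPKM, median-of-ratios scaling, quantile normalization, FPKM, TPM and covered bases scaled to a common total from the StringTie files, array weights, the replicate number as a block, and leaving out each library. Added after the data were seen were protein-coding genes only, genes with about 30 reads or more on average, the same without any value of 0, and a robust prior. Rows with 1 to 5 values entered no test.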

Results

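RNA was sequenced from human pulmonary arterial endothelial cells, the primary cells that line the arteries of the lung. The labels name 3 control libraries and 3 libraries from cells given small interfering RNA (siRNA) against OLA1, an ATPase of the Obg family. They describe 24 h of transfection followed by 24 h of rest for all samples, while the transfection entry of the controls reads none, and neither a non-targeting siRNA nor a mock transfection is named as a background. Libraries were made from the 3′ ends of polyadenylated RNA. The steps between FPKM values of long genes placed the depth at about 7520000, 7750000 and 8970000 reads for control replicates 1 to 3 and at about 7520000, 8660000 and 5990000 reads for OLA1 siRNA replicates 1 to 3. The labels do not say whether the replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. The comparison asks how gene expression differs between libraries labelled as given OLA1 siRNA and control libraries. No library is labelled as given another siRNA, and the labels leave open whether the controls were transfected. For every gene below, an effect of OLA1 loss therefore cannot be told apart from a response to the transfection or to any siRNA.

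OLA1 itself could not serve as a check of the labels. The rows of the FPKM table used here did not include it, and it was not analysed here from that table. In the transcript files of the 6 libraries OLA1 was listed at 0 FPKM in every one, and so were the abundant transcripts FTL, GAPDH and TMSB4X, so this 0 says nothing about knockdown. The groups below therefore rest on the labels alone.

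Interferon-induced genes rose together in the siRNA libraries. The interferon response list holds 41 genes, of which 8 were measured. All 8 were higher, both over all genes tested and adjusted over the list alone, with a median log2 fold change of 5.53. IFI6 (ENSG00000126709), a mitochondrial and endoplasmic reticulum protein induced by interferon, went from 22.1 ± 2.53 to 2403 ± 349 FPKM (SD, n = 3 per group). IFIT1, which binds foreign RNA, and its partner IFIT3 went from 0.373 ± 0.213 to 124 ± 6.1 FPKM and from 3.77 ± 1.29 to 409 ± 65.2 FPKM. ISG15, a ubiquitin-like modifier, went from 15.4 ± 3.35 to 959 ± 44.7 FPKM, and USP18, the protease that removes it, from 6.88 ± 3.21 to 159 ± 15.7 FPKM. The chemokine CXCL10 went from 0.441 ± 0.272 to 54.3 ± 23.8 FPKM and the membrane tether BST2 from 15.3 ± 1.98 to 235 ± 25.8 FPKM. On the log2(FPKM + 1) scale, which understates the change of low genes, these rises were 6.70 (SE 0.157) for IFI6, 6.51 (SE 0.165) for IFIT1, 6.45 (SE 0.259) for IFIT3 and 5.89 (SE 0.176) for ISG15, with limma adjusted p-values of 8.5e-05, 8.5e-05, 0.000298 and 0.000139. The camera test of the list against all other genes gave an adjusted p of 3.3e-20, and an adjusted p = 0.00248 with an estimated correlation. RTP4 and IFIT5, which belong to the same class of induced genes but not to the list, rose by 4.16 (SE 0.127) and 3.78 (SE 0.203) on the log2 scale.

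**Figure D1:**
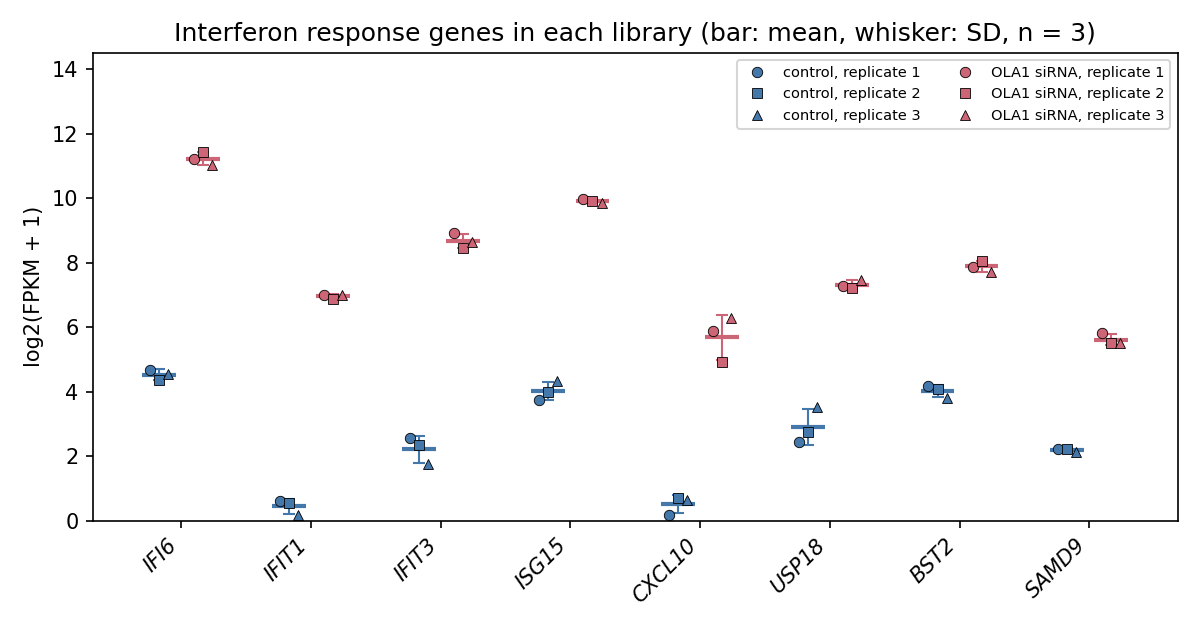
Expression of the 8 measured interferon response genes as log2(FPKM + 1) in each of the 6 libraries, with the mean (bar) and SD (whisker) of the 3 replicates per group. Every OLA1 siRNA library lies above every control library for each gene, with IFI6 at 2071 FPKM or more against at most 24.4 FPKM.

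In GRCh37 coordinates, the build of the transcript files, IFI6 lies on chromosome 1 at 27992575 to 27998703 on the minus strand, and ISG15 on the same chromosome at 948877 to 949920 on the plus strand. IFIT3, IFIT1 and IFIT5 are neighbours on the plus strand of chromosome 10, at 91087754 to 91100725, 91152303 to 91166244 and 91174325 to 91180754. The positions span whole protein-coding genes, introns included.

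Over the 3013 genes tested, 44 were higher and 30 lower in the siRNA libraries (limma, Benjamini-Hochberg adjusted p under 0.05). Of the protein-coding genes, 839 were tested, 30 were higher and 12 lower. All 74 called genes had groups that did not overlap, as had 24% of the tested genes, where chance gives 10% for 3 against 3. Of the called genes, 14 were listed at 0 in all 3 libraries of a group, and a 0 in this table can be a failed estimate. The counts moved by over 1.5 times without control replicate 2 (24 higher and 18 lower), control replicate 3 (52 lower), siRNA replicate 1 (27 higher and 15 lower), siRNA replicate 2 (11 lower) or siRNA replicate 3 (19 lower). With protein-coding genes alone, a setting chosen after the data were seen, 118 genes were higher and 56 lower.

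**Figure D2:**
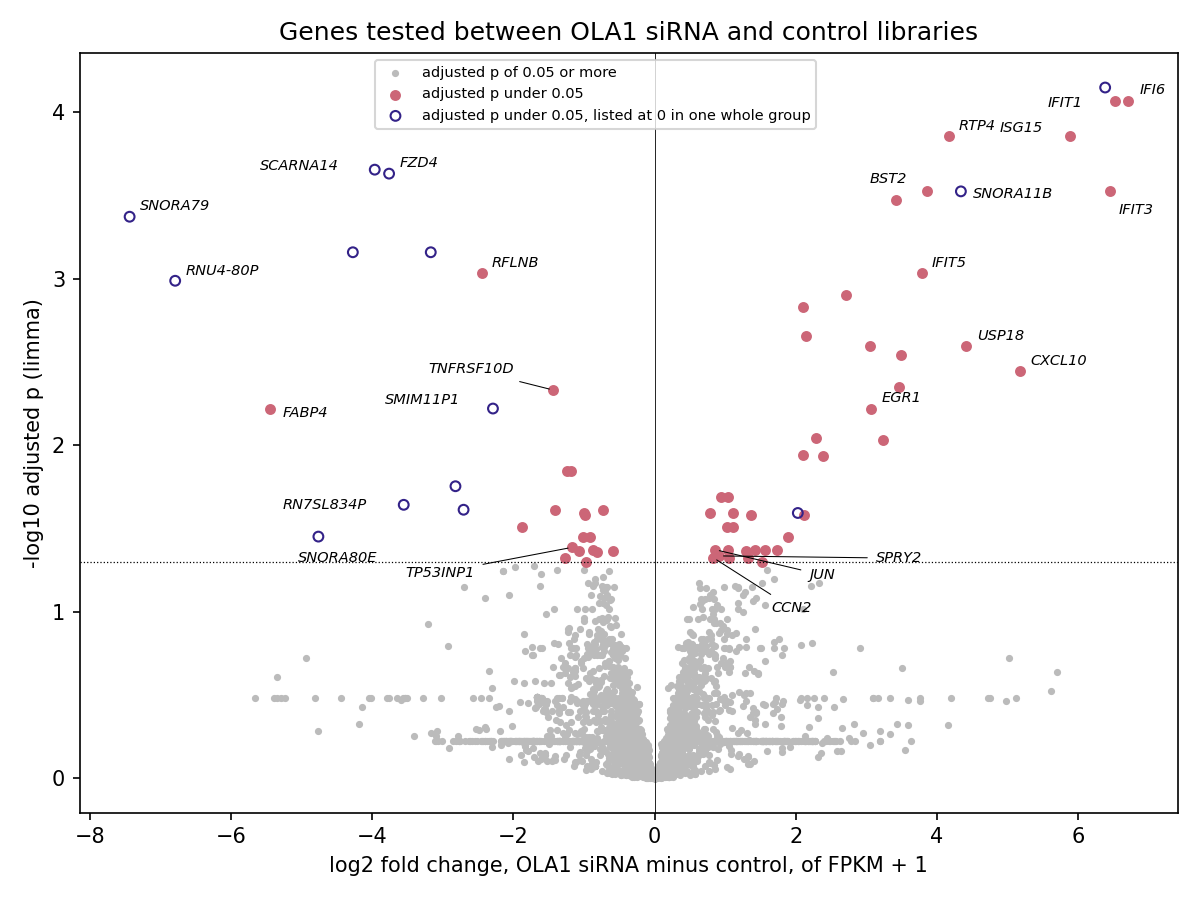
Log2 fold change of FPKM + 1, siRNA minus control, against −log10 of the limma adjusted p for the 3013 genes tested; the dotted line marks an adjusted p of 0.05, and open circles are called genes listed at 0 in one whole group. The interferon-induced genes lie at the upper right, with IFI6 at 6.70, and FABP4 lies at −5.45.

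Among the genes that fell, FABP4, the fatty acid binding protein of fat cells and small-vessel endothelium, went from 112 ± 30.5 to 1.81 ± 1.58 FPKM (SD, n = 3), a log2 fold change of −5.45 (SE 0.472) at a limma adjusted p of 0.00602; without control replicate 2 or siRNA replicate 1 its adjusted p was 0.0547 and 0.0539. RFLNB, a regulator of filamin, went from 22 ± 2.01 to 3.19 ± 0.203 FPKM, and TNFRSF10D, a decoy receptor for the death ligand TRAIL, from 13.7 ± 0.456 to 4.45 ± 0.181 FPKM, with log2 fold changes of −2.45 (SE 0.133) and −1.43 (SE 0.117). FZD4, a Wnt and norrin receptor of vascular endothelium, stood at 12.8, 11.5 and 13.4 FPKM in control replicates 1 to 3 and was listed at 0 in the 3 siRNA libraries. FZD4 lies on the minus strand of chromosome 11 at 86656721 to 86666437 and FABP4 on the minus strand of chromosome 8 at 82390654 to 82395468. Small RNA genes and pseudogenes also led the falls: SNORA79 at 284, 137 and 131 FPKM, RNU4-80P at 83.0, 80.2 and 197 FPKM, SNORA80E at 15.3, 14.8 and 76.8 FPKM, SCARNA14 at 15.7, 15.1 and 13.1 FPKM, RN7SL834P at 11.4, 5.52 and 19.1 FPKM and SMIM11P1 at 4.17, 4.04 and 3.49 FPKM in the controls were listed at 0 in the siRNA libraries. SNORA11B was listed at 0 in the controls and stood at 18.7, 16.2 and 23.4 FPKM in the siRNA libraries. Some of these values rest on few reads, about 2.8 per library for SMIM11P1, 8 for SCARNA14, 9 for SNORA11B, 14.3 for RN7SL834P and 21 for SNORA80E on average over the 6 libraries, and a value of 0 can be a failed estimate. The libraries were made from polyadenylated RNA. Whether these values come from the small RNAs themselves or from reads shared with other genes was not tested. SNORA80E and RN7SL834P lost their calls when single libraries were left out, with adjusted p-values up to 0.149 and 0.115.

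The list of ERK target and feedback genes was chosen because the title of the series concerns ERK. Of its 24 genes 6 were measured, with 3 higher members and no lower member, over all genes and adjusted over the list alone. EGR1, an immediate-early transcription factor, rose from 1.23 ± 0.334 to 18.1 ± 6.03 FPKM (SD, n = 3), by 3.07 on the log2 scale (SE 0.267; limma adjusted p of 0.00602). JUN, a subunit of the transcription factor AP-1, rose from 41.2 ± 2.78 to 75.6 ± 6.79 FPKM, and SPRY2, a feedback inhibitor of receptor signalling to ERK, from 3.13 ± 0.229 to 6.81 ± 0.795 FPKM. JUNB, IER3 and PHLDA1 did not pass, with log2 fold changes of 0.29, −0.55 and −0.56. The camera test of the list gave an adjusted p of 0.0196, against an adjusted p = 0.329 with an estimated correlation, and 0.267 without control replicate 3 and 0.0558 without siRNA replicate 2. SPRY2 lost its call when any 1 library was left out (adjusted p 0.091 to 0.196), and JUN without control replicate 1 or 2 or siRNA replicate 1 or 2 (adjusted p 0.067 to 0.114), each with its direction kept.

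Of the 30 genes of the endothelial identity list 4 were measured, and none of them passed over all genes. Adjusted over the list alone, 3 of the 4 were lower, and its median log2 fold change was −1.45; a list of 4 was too short for the planned camera test. The transcription factor SOX18 stood at 24.9 ± 13 and 2.66 ± 0.972 FPKM (SD, n = 3) and the tight-junction protein CLDN5 at 38.4 ± 17.6 and 6.14 ± 2.26 FPKM in control and siRNA libraries, with log2 fold changes of −2.71 and −2.40. SOX17, another endothelial transcription factor, stood at 24.4 ± 4.18 and 16.9 ± 1.75 FPKM, and the anticoagulant receptor THBD, at 11.5 ± 6.72 and 6.88 ± 1.38 FPKM, did not pass. These members were picked for naming after their values were seen. Control replicate 3 stood apart from control replicates 1 and 2 in several of them: SOX18 was at 10.8 FPKM there against 36.2 and 27.8 FPKM, and CLDN5 at 18.6 against 52.3 and 44.4 FPKM.

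**Figure D3:**
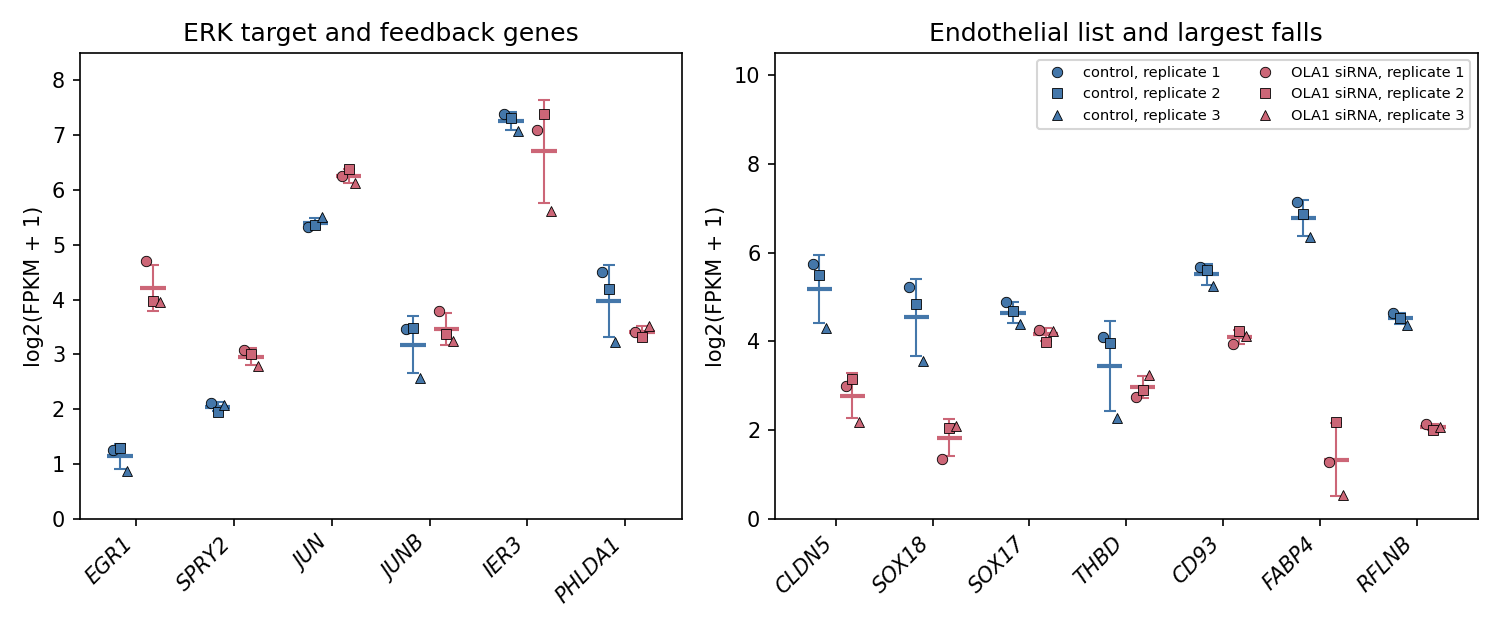
Expression as log2(FPKM + 1) of the 6 measured ERK target and feedback genes (left) and of the 4 endothelial identity genes with 3 genes that fell (right) in each library, with the mean (bar) and SD (whisker) of the 3 replicates per group. The 3 genes that fell are CD93, FABP4 and RFLNB. CD93 is outside the endothelial identity list and the rule for named genes and was picked for the panel. EGR1 rose from 1.23 to 18.1 FPKM, and control replicate 3 lies below the other controls for CLDN5 and SOX18.

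Of 42 gene lists, 28 had a measured member and 4 had the 5 members needed for a test. The nuclear genes of oxidative phosphorylation had 7 measured members of 59 listed, none called over all genes or over the list alone, with a camera adjusted p of 0.448. The result holds for these 7 alone, and among them NDUFB10 had an SE of 2.30. The median log2 fold change of the list was 0.05, with −0.02 without siRNA replicate 3 and 0.07 to 0.26 without any other 1 library. The BMP and SMAD signalling list had 5 measured members of 22 listed, none called, with a camera adjusted p of 0.448. Its median was 0.47, but −0.03 without control replicate 3. CCN2, a matricellular protein on both the TGF-beta and the YAP/TAZ list, rose from 524 ± 48.0 to 933 ± 109 FPKM (SD, n = 3; limma adjusted p of 0.0474), but its adjusted p was 0.179 after quantile normalization and 0.0659 to 0.166 when any 1 library was left out. TP53INP1, a p53 target that takes part in autophagy, fell from 6.19 ± 0.977 to 2.19 ± 0.336 FPKM (limma adjusted p of 0.0411), with an adjusted p of 0.0696 after quantile normalization and of 0.0663 to 0.174 when any 1 library was left out. Adjusted over the list alone but not over all genes, both measured NF-kB inflammatory genes, CXCL1 and IL1A, were higher and FTL of the NRF2 antioxidant list was lower; these members were named after their values were seen. CXCL1 stood at 63.1 ± 19.8 and 188 ± 34.5 FPKM in control and siRNA libraries. The lists for the integrated stress response and for the unfolded protein response of the endoplasmic reticulum had 3 measured members each and the heat shock list 2, with no called member over all genes or over the list alone. The members of these lists did not share a direction. HSPA5, the main chaperone of the endoplasmic reticulum, stood at 156 ± 45 and 199 ± 14.1 FPKM in control and siRNA libraries. In the same list SDF2L1 stood at 27.2 ± 11.6 and 31.2 ± 2.78 FPKM and MANF at 58.2 ± 3.57 and 47.7 ± 12.5 FPKM. The heat shock protein HSPA1A stood at 11.3 ± 2.82 and 17.5 ± 3.39 FPKM, and HSPB1 of the same list at 751 ± 94.3 and 517 ± 93.0 FPKM.

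Few markers of other cell types had values in all 6 libraries. The highest value of any smooth muscle marker was 0.069 FPKM, over 2 markers with 6 values, and the only fibroblast marker with 6 values reached 0.122 FPKM. The leukocyte, epithelial and erythroid markers with 6 values, 4, 3 and 4 in number, were listed at 0 in the 6 libraries, which in this table can be a failed estimate.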

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

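The tests of explanations in this part were chosen or worded after the results were seen, except the splits of the libraries for the interferon and ERK lists.

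Signals above the control level were found in rows of the gene table that the comparisons do not use because 1 or more cells are empty. Of 1509 such rows with at least 2 values per group, 3 had every siRNA value at 1 FPKM or more and at least 4 times the highest control value, and 0 had the opposite by the same rule, which is no statistical test. NRIR, an antisense RNA known as a regulator of the interferon response, stood at 2.07 and 1.71 FPKM in siRNA replicates 2 and 3 (mean 1.89) against 0.138, 0 and 0.116 FPKM in the controls. The pseudogene ANO7L1 stood at 2.6 and 6.26 FPKM (mean 4.43) and the long intergenic RNA ENSG00000265519 at 3.5, 1.52 and 6.58 FPKM (mean 3.87), each listed at 0 in the controls with a value.

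In the transcript files, 7 of the 995 list genes looked up were listed at 0 in the 3 controls and above 0 in at least 2 siRNA libraries, and 3 showed the opposite. This look-up was no statistical test. The values were taken to come from the strand opposite to most mRNAs, so they were not read as mRNA levels of these genes. The highest siRNA values of the 7 were 451.7 FPKM for MRPL20, 165 for IFI6, 22.1 for CCN2, 9.65 for CYP51A1, 9.26 for NRP1, 6.23 for UHRF1 and 5.97 for PINK1. MRPL20, IFI6, CCN2, CYP51A1 and UHRF1 were at 0 in siRNA replicate 2. That library had 1117 transcripts above 0, against 1688 and 1630 in siRNA replicates 1 and 3. The 3 with the opposite stood in control replicates 1 to 3 at 122, 152 and 212 FPKM for MRPS7, 11.4, 0 and 16.1 FPKM for EIF4A2 and 1.31, 2.54 and 0 FPKM for PFKFB3.

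The interferon response list rose by a median of 5.53 on the log2 scale. A difference in scaling between the libraries, which would move all genes alike, is argued against by the 3005 tested genes outside the list, whose log2 fold change had a median of −0.041 and quartiles of −0.499 and 0.343, where the lowest member of the list was at 3.42. Leukocyte RNA stays open, since the 4 leukocyte markers with 6 values were listed at 0 in the siRNA libraries (highest value 0.0 FPKM), and a 0 here can be a failed estimate. A response to the transfection or to any siRNA cannot be told apart from an effect of OLA1 loss, because 0 libraries are labelled as given another siRNA and the labels leave open whether the controls were transfected. An effect of OLA1 knockdown itself therefore remains possible and untested.

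Control replicate 3 lay toward the siRNA libraries in many of the genes called without it. Over 47 such protein-coding genes outside the interferon list, its median position was 35.4% of the way from the other controls to the siRNA libraries. The quartiles were 6.1% and 66.2%, on the log2 scale, and 40 of the 47 lay on the siRNA side. The same measure gave 2.2% over 17 genes for control replicate 1 and −0.8% over 12 genes for control replicate 2. The gene sets differ, and the 17 and 12 genes were called with control replicate 3 among the controls, which favours genes where it did not deviate. Over all tested genes control replicate 3 correlated with control replicates 1 and 2 at 0.715 and 0.692. With siRNA replicates 1 to 3 it correlated at 0.68, 0.679 and 0.683. Mixing of siRNA RNA into control replicate 3 is argued against by the 8 interferon genes, where its median share of the siRNA excess was −0.13% and its highest 3.54%. No label gives a batch or a culture difference for this library, so no biological explanation was tested.

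Of the 1330 tested genes with about 30 reads or more, 20 had exactly 3 values of 0, and 6 of them were at 0 in one whole group, FZD4, SNORA79 and RNU4-80P among them. Zeros spread at random over the libraries would give 2, and the exact binomial test (one-sided) gave a p of 0.0113, which argues against failed estimates at random as the whole cause of these 6. Which of the 6 are true changes stays open: NDUFB10, at 0 in control replicate 2 and siRNA replicate 1 and at 38.1 to 57.7 FPKM in the other 4 libraries, shows that failed estimates occur in protein-coding genes too. An effect of the knockdown on them was not tested apart from this.

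Over the 10 splits of the 6 libraries into 3 and 3, 1 split, the real one, gave 74 called genes, and the highest of the others gave 8. The real split gave an unadjusted camera p of 8.3e-21 for the interferon list, where the smallest of the others was 0.0101, and 0.00982 for the ERK list, where the smallest of the others was 0.0171. With 10 splits no share under 0.05 can be reached.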

How the results depend on the processing

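The settings named as added were chosen after the data were seen. The interferon list stayed past its threshold with a median log2 fold change of 5.38 to 6.34 in all alternatives that gave it a value. With the StringTie values fewer than 5 of its genes reached a mean of at least 1, so the list was not tested there. OLA1 was tested under no alternative; the StringTie files listed it at 0 in the 6 libraries. Calls numbered 44 higher and 30 lower. They were 25 and 12 without an expression filter (10865 genes tested), 17 and 8 with the replicate block, 59 and 47 with array weights, 0 and 5 with StringTie FPKM, 0 and 5 with StringTie TPM, and 0 and 0 with covered bases, where limma gave 89, 99 and 87 genes an unadjusted p under 0.05. Added settings gave 118 and 56 (protein-coding genes only), 74 and 59 (30 reads or more on average) and 115 and 94 (the same with no value of 0, which removes genes that fell to 0). The StringTie values were taken to come from the opposite strand and also differ in annotation and in the genes above 0; the cause of these moves was not tested. Leaving out 1 library gave 24 to 56 higher and 11 to 52 lower genes.

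The ERK list lost its call at a mean of 5 FPKM (median 0.293, adjusted p 0.196), with an estimated correlation (0.576, 0.329), and with added settings: protein-coding genes only (0.576, 0.26), 30 reads on average (0.576, 0.0724) and no value of 0 (0.576, 0.0863). Over its alternatives the adjusted p was 0.00333 to 0.329, and the median 0.453 to 0.666 with 1 library left out. The cause was not tested.

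Of the 25 named genes, 25 kept their calls with a pseudocount of 0.1, median-of-ratios scaling, array weights and the added robust prior, 23 with quantile normalization, 19 without a filter, 18 to 22 with 1 library left out and 15 with the replicate block, where CXCL10, EGR1 and TNFRSF10D were among the 10 that did not pass (adjusted p of 0.0701, 0.0535 and 0.0996). With StringTie FPKM, TPM and bases, 4, 4 and 6 named genes could be tested, and 0 kept their calls. IFI6 stood at 4.62, 4.43 and 4.55 there (limma adjusted p of 0.705, 0.681 and 0.656). IFIT1 stood at 1.25 with bases (limma adjusted p of 0.656). Only with the StringTie files did any reverse: FZD4 (0.739, 0.268 and 0.82 with StringTie FPKM, TPM and bases) and JUN (−0.939 with bases), none called. Because the StringTie values were taken to come from the strand opposite to most mRNAs, they cannot test the calls of these mRNAs.

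The replicate numbers did not pair the libraries: deviations of same-numbered libraries correlated at 0.019, −0.073 and 0.04 over all tested genes, and not every library correlated best with its own number. With the number as a block, 24 of the 74 calls remained. The depth was about 5990000 to 8970000 reads per library, and what it can detect per gene was not tested.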

Other observations

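The fit on protein-coding genes alone and the choice of the genes named here came after the data were seen. That fit (limma, 839 genes) gave 118 higher and 56 lower genes. In the planned fit over all 3013 genes, 30 of these 839 were higher and 12 lower. Passing here therefore does not mean passing in the planned fit. IFNB1, the gene of interferon beta, was listed at 0 in the 3 controls and stood at 2.62, 0.698 and 2.78 FPKM in siRNA replicates 1 to 3 (adjusted p of 0.0238), from only about 6.1 reads per library. MAVS, the mitochondrial adaptor through which cytoplasmic RNA sensors signal to the interferon genes, fell from 4.63 ± 0.539 to 2.14 ± 0.211 FPKM (SD, n = 3; limma adjusted p of 0.00859). The chemokine CXCL1 rose from 63.1 ± 19.8 to 188 ± 34.5 FPKM, and the growth factors FGF2 and BDNF from 1.25 ± 0.52 to 9.33 ± 4.83 FPKM and from 0.573 ± 0.584 to 6.41 ± 2.96 FPKM. Control replicate 3 lay above the other controls in these, at 1.25 FPKM for BDNF against 0.198 and 0.275, at 1.84 FPKM for FGF2 against 0.986 and 0.907, and at 85.9 FPKM for CXCL1 against 52.1 and 51.2.

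Within the same fit SOX18 and CLDN5 fell (limma adjusted p of 0.0084 and 0.0112), but they did not pass over all genes (0.0708 and 0.0829). FTL, the light chain of the iron store ferritin, fell from 1202 ± 222 to 597 ± 44 FPKM (SD, n = 3). The limma adjusted p of FTL was 0.00833 in this fit and 0.0563 over all genes. MT2A, a metallothionein whose family members share sequence, rose from 6227 ± 4230 to 17677 ± 3601 FPKM (adjusted p of 0.0371). Control replicate 3 carried 11106 FPKM of it, against 3608 and 3965 FPKM in the other controls. CEBPB, of the integrated stress response list, stood at 3.96 ± 0.974 and 8.88 ± 2.94 FPKM in control and siRNA libraries and passed in this fit (adjusted p of 0.0445) but not over all genes (0.189); it was the only 1 of the 3 measured members to pass.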
